A study of Escherichia coli with 9 samples.

How the data were processed

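Total RNA was sequenced from 9 libraries of Escherichia coli LC-E18, 3 for each of 3 guide RNAs. Per the labels, RNA was purified with TRIzol, libraries were made with a stranded mRNA kit, and Bowtie2 2.3.4 and featureCounts 1.6.1 were used. The genome build, the gene annotation and the strand setting are not given in the sources used here. The deposited count table holds raw read counts per gene, 1 column per library, with no normalization. It has 4505 genes and features, of which 4489 were matched by locus tag to the RefSeq annotation of the MG1655 assembly ASM584v2. Of the 16 others, 6 are vector features: sgRNA, dCas9, tetR, kan, colE1 and GFPmut2. The authors also deposited a DESeq2 result table for each guide against control. In these tables the deposited baseMean is a signal, the mean normalised count over the libraries of the authors' fit. The deposited fold changes are on the log2 scale. The deposited standard errors and Wald statistics are scores, and the p-value and adjusted p-value columns come from the authors' test. A column of absolute log2 changes in 1 of these tables was not used here.

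Samples were grouped by guide as the labels name them. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these samples only. The total count per library ranged from 18885701 to 46568763. Limits given for a count of 0 cover counting error only. The count table was analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 4369 genes in the fit of all 9 libraries and 4373 in a fit without AGGAA replicate 2. Libraries were scaled by trimmed mean of M-values (TMM). The test was edgeR's 2-sided quasi-likelihood F test on group means, with 1 estimate of the spread shared by all libraries and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. The standard error (SE) of a log2 change is its size divided by the square root of F. CPM, counts scaled to library size, use the TMM-scaled sizes and are given as mean ± SD. Called genes are those past the threshold. The 3 comparisons are each guide against control and the guides against each other. DESeq2 1.42.0 was run as another test and to refit the authors' tables. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for reading tables and drawing.

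The groups, comparisons, tests, 40 gene lists, most alternative settings and the rule for naming genes were chosen before the data were examined. The lists hold 1109 entries, all matched to the count table, and cover growth, stress, surface structures and metabolism. A list was tested if it had at least 4 tested members, which left 39. The test was camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists. Beside it stand camera with an estimated correlation and fry. Members past the threshold were counted over all genes and adjusted over the list alone. Named genes are the 8 most negative and 8 most positive log2 changes among called genes with a mean of at least 10 counts and no overlap in CPM between the groups, or 5 of each for the guides against each other. Up to 4 called members of each list past the camera threshold, smallest p first, were added. rRNA and tRNA genes were left out of this rule. Any other gene, and any gene named from the fit without AGGAA replicate 2, was chosen after its values were seen. Neighbours are genes next to each other in the RefSeq gene order, with strand not used, and pairs of neighbours among called genes were compared with 10000 random gene sets in a 1-sided permutation test.

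The overlap of both guides' calls was compared with independent lists and with 50 simulations of unchanged groups against a shared set of simulated control libraries. The correlation and covariance of both guides' log2 changes across genes were set beside the simulated ones. The alternatives were RLE size factors, library totals alone, no count filter, a mean of at least 50 counts, DESeq2, only the 6 libraries compared, the replicate number as a block, no rRNA and tRNA features, and each library left out in turn. After the data were seen, fits of ACCCA without AGGAA replicate 2, DESeq2 or the block without that library, and no vector features were added. A planned test for guide seed sites upstream of lowered genes was not run, because no genome sequence was used here, and neither were its alternatives or the naming of genes by such sites. The methods were tested on simulated counts with genes changed by known amounts. With all 9 libraries, 90% of genes simulated at a log2 change of -2 were called for AGGAA and 80% for ACCCA. At a log2 change of -1 the shares were 60% and 45%. Of unchanged genes, 0.14% and 0.07% were called. Without AGGAA replicate 2 the shares at -1 were 87.5% for both guides. A simulated shift of 1 list with ACCCA was found at an adjusted p of 1.57e-14 by camera, with 0 of the other lists called. Genes were drawn independently of each other there, so this does not show how camera performs where list members move together.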

Results

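RNA was sequenced from 9 libraries of Escherichia coli LC-E18, a strain that makes dCas9 from a promoter induced by anhydrotetracycline (aTc). dCas9 is a Cas9 protein that binds DNA under the direction of a guide RNA and does not cut it. The cells carried a plasmid with a control guide, the guide AGGAA_non1 or the guide ACCCA_non1, hereafter AGGAA and ACCCA, with 3 libraries per guide, and were collected after 3 h with 1 nM aTc. The control libraries held 46568763, 25314834 and 39534526 counts. The AGGAA libraries held 25814412, 20330913 and 24008190, and the ACCCA libraries 18885701, 22835440 and 20101462. Ribosomal RNA took 0.0627% ± 0.031 of the counts in control, 0.061% ± 0.053 with AGGAA and 0.055% ± 0.0451 with ACCCA (SD, n = 3). Features of the vectors took 25.0% ± 1.15, 24.3% ± 3.59 and 28.7% ± 0.984 of the counts (SD, n = 3). The noncoding RNA ssrA, the transfer-messenger RNA that rescues stalled ribosomes, alone took 9.27% ± 0.641, 9.97% ± 1.82 and 11.2% ± 0.178 (SD, n = 3).

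One library stood apart from the others. AGGAA replicate 2 lay at 61.5 on the first principal component, which held 67.6% of the variance, and the other 8 libraries lay between -9.04 and -5.43. Across genes, which are not independent replicates, its log2 CPM had a Pearson correlation of 0.9154 and 0.9194 with AGGAA replicates 1 and 3, against 0.9932 between those. In this library 255 genes lay more than 4-fold from the mean of the other AGGAA replicates. The same count was 53 and 49 for AGGAA replicates 1 and 3, whose comparison includes replicate 2, 0 for each control library and 4 to 7 for the ACCCA libraries. The second component, with 15.1% of the variance, held the ACCCA libraries at 11.21 to 15.9 and the control libraries and AGGAA replicates 1 and 3 at -10.55 to -5.29. The counts of called genes in each comparison are therefore given with all 9 libraries and without AGGAA replicate 2. Leaving that library out was planned for AGGAA, and was chosen after the data were seen for ACCCA.

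**Figure D1:**
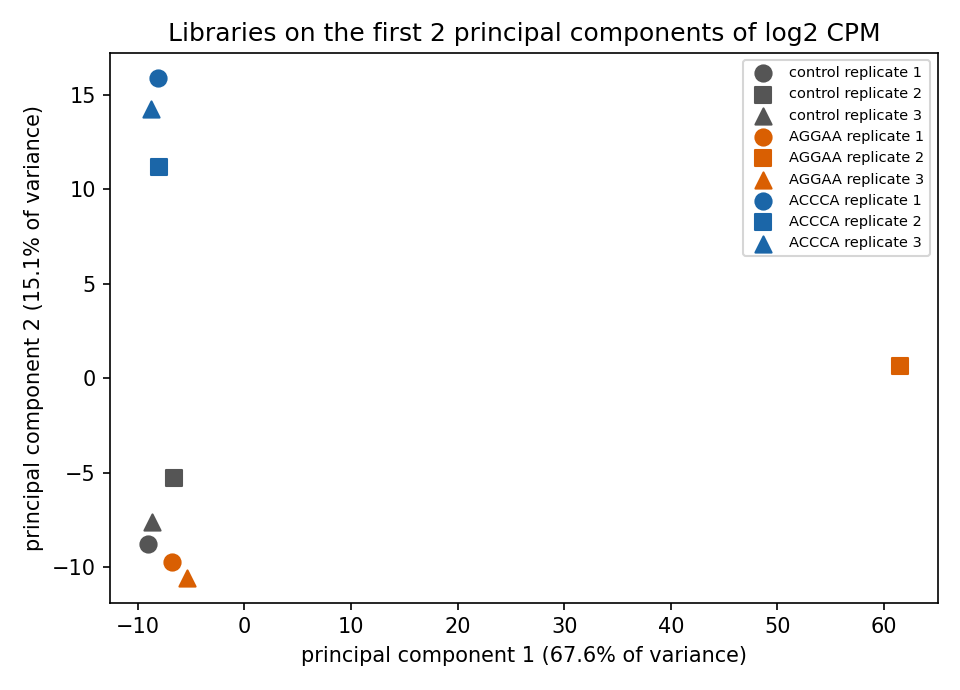
Each point is 1 library on the first and second principal components of log2 CPM (67.6% and 15.1% of the variance), with colour for the guide and shape for the replicate number. AGGAA replicate 2 lies at 61.5 on the first component and the 3 ACCCA libraries lie above 11 on the second.

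The comparison of AGGAA with control asks which transcripts change when dCas9 is given this guide. The largest decreases among called genes were in glyQ and glyS, neighbouring genes for the α and β subunits of glycyl-tRNA synthetase, which are essential for growth. glyQ (b3560) fell from 76.8 ± 2.98 to 10.4 ± 1.99 CPM (SD, n = 3), a 7.37-fold decrease with a log2 change of -2.88 ± 0.14 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 9.45e-05). glyS (b3559) fell from 290 ± 11.8 to 51.2 ± 8.7 CPM (SD, n = 3), a log2 change of -2.50 ± 0.13 (SE, adjusted p = 9.45e-05). The genes of formate dehydrogenase-O, a respiratory enzyme, and of its maturation protein FdhD also fell. fdhD (b3895) had a log2 change of -1.81 ± 0.13 (SE, adjusted p = 0.000491), fdoG (b3894) of -1.29 ± 0.12 (adjusted p = 0.00283) and fdoI (b3892) of -1.27 ± 0.15 (adjusted p = 0.0097), each with 3 libraries against 3. hdhA (b1619), for 7α-hydroxysteroid dehydrogenase, fell by 1.78 ± 0.16 on the log2 scale (SE, adjusted p = 0.00207). udk (b2066), for uridine-cytidine kinase, fell by 1.53 ± 0.19 (SE, adjusted p = 0.0145) and yibN (b3611), for a rhodanese-like protein, by 1.30 ± 0.09 (SE, adjusted p = 0.000491).

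Only 3 genes were called higher with all 9 libraries. ybaL (b0478), for a predicted cation antiporter, rose by 1.73 ± 0.19 on the log2 scale (SE, n = 3, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00728). hha (b0460), for a nucleoid-associated regulator, and its neighbour tomB (b0461), for the partner protein of Hha, rose by 0.79 ± 0.09 and 0.58 ± 0.09 (SE, adjusted p = 0.0097 and 0.0385). The other called genes, chosen after their values were seen, were all lower: yacL, yiiG, degS, rimO, rpsP and ydfG, at -1.14 to -0.62, and leaving out any 1 of the control libraries ended all 6 of these calls. Among these, degS is for the protease that starts the σE envelope response, rpsP for ribosomal protein S16 and rimO for an enzyme that modifies ribosomal protein S12. The calls of glyQ, glyS, fdhD, hdhA, yibN and fdoG held with each library left out, and that of fdoG ended with only the 6 libraries compared (adjusted p = 0.0567, the highest of its settings). Leaving out any 1 of the 3 control libraries ended the calls of udk, fdoI, ybaL, hha and tomB, with adjusted p from 0.0678 to 0.284. Over all settings tried, adjusted p reached 0.126 for udk, 0.118 for fdoI, 0.108 for ybaL, 0.125 for hha and 0.284 for tomB. Those of udk and tomB also ended without AGGAA replicate 1 (adjusted p = 0.0883 and 0.14), and those of fdoI and tomB without AGGAA replicate 3 (adjusted p = 0.0526 and 0.0768).

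**Figure D2:**
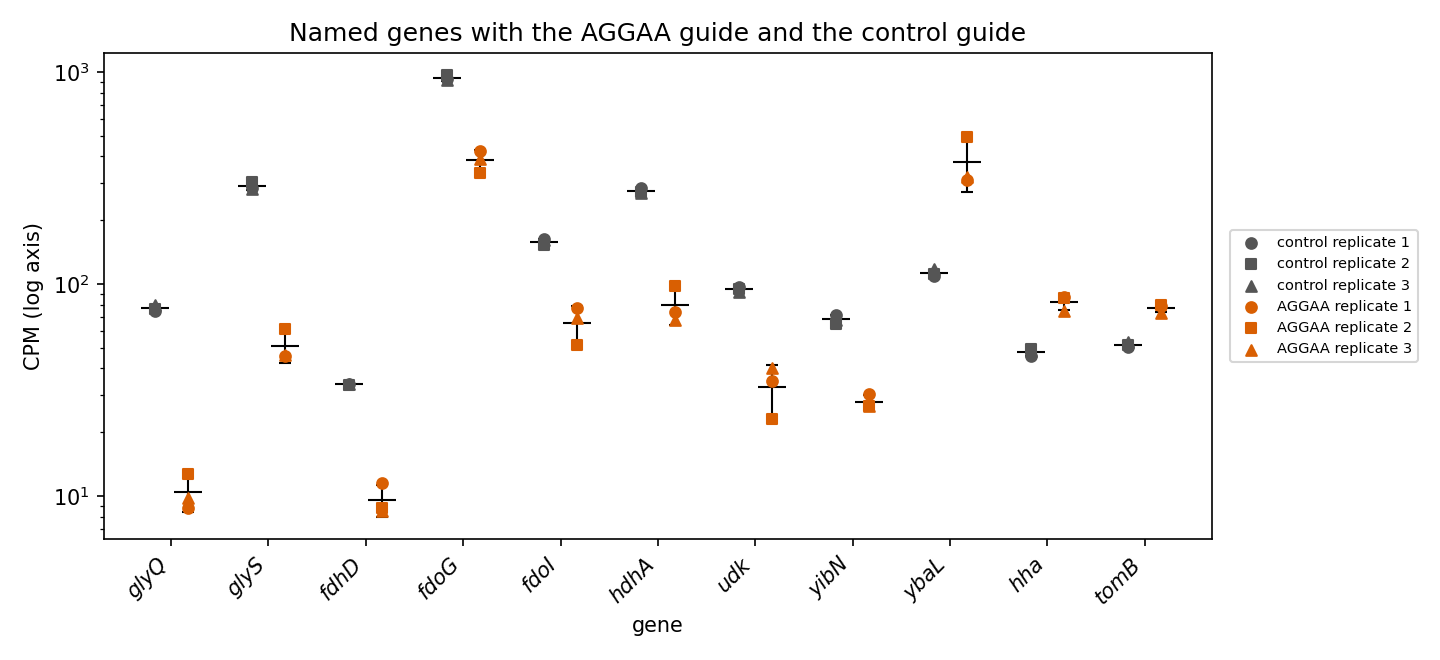
Points are CPM on a log axis in each library with the control guide (grey) and AGGAA (orange), with the mean and SD of 3 libraries as black bars. glyQ lies near 76.8 CPM with the control guide and near 10.4 CPM with AGGAA, and replicate 2 (square) lies with the other AGGAA replicates in glyQ, glyS and fdhD.

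Among 4369 genes, 14 were lower and 3 higher with AGGAA than with the control guide (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 9 were lower and 1 was higher by at least 2-fold, and 450 genes had an unadjusted p under 0.05. DESeq2 called 62 lower and 39 higher, a share of lower calls of 61.4% against 82.4%. Without AGGAA replicate 2, 47 were lower and 37 higher, 13 and 1 by at least 2-fold, with 611 at an unadjusted p under 0.05, and these held all 14 and all 3 of the former calls. The count of lower genes was 6 without any 1 of the control libraries and 7 without AGGAA replicate 1 or 3. The count of higher genes was 0 without any 1 of the control libraries. At an adjusted p below 0.05, the authors' deposited DESeq2 table gives a lower level for 94 genes and a higher level for 113. A DESeq2 refit of 5 libraries, without AGGAA replicate 2, differed from its log2 changes by at most 1.25e-09. The same refit with that library, of 6 libraries, differed by up to 4.14 and gave 52 lower and 34 higher. The deposited values are therefore those of a fit without AGGAA replicate 2. Called genes of either direction lay next to each other in the genome more often than random sets. The random sets draw genes singly, while neighbouring genes can share a transcript, so more pairs do not show where a guide acts. The 14 lowered genes formed 3 neighbouring pairs, against a mean of 0.042 and a maximum of 2 in 10000 random sets (permutation p = 0.0001, the smallest these draws can give). The 3 raised genes formed 1 pair, hha-tomB (permutation p = 0.0015). The lowered runs were glyS-glyQ and fdoG-fdhD-yiiG. In the fit without AGGAA replicate 2, 47 lowered genes formed 15 pairs and 37 raised genes 11, against a maximum of 4 in random sets for each (permutation p = 0.0001).

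In the fit without AGGAA replicate 2, genes chosen after their values were seen extended these runs. The formate dehydrogenase run grew to fdoI-fdoH-fdoG-fdhD-yiiG, at -1.75 to -0.88, and a run around the gene for ribosomal protein S16, rplS-trmD-rimM-rpsP, lay at -0.70 to -0.40. uacT, for a urate transporter, fell by 1.88 ± 0.16 on the log2 scale (SE, n = 2 against 3, edgeR adjusted p = 0.000133, 0.381 with all 9 libraries, and 3.57e-30 to 0.781 over the settings). glpX, for a fructose-bisphosphatase, fell by 1.43 ± 0.10 (SE, adjusted p = 2.46e-05, 0.054 with all 9 libraries, and 4.17e-35 to 0.368 over the settings). The toxin gene mazF and its antitoxin gene mazE fell by 0.52 ± 0.09 and 0.54 ± 0.11 (SE, adjusted p = 0.0176 and 0.0453, 0.179 and 0.237 with all 9 libraries, at most 0.781 over the settings). ilvB and ilvN, for the subunits of an acetohydroxy acid synthase that makes branched-chain amino acids, rose by 0.65 ± 0.08 and 0.71 ± 0.12 (SE, adjusted p = 0.00257 and 0.0137, 0.126 and 0.132 with all 9 libraries, at most 0.597 and 0.689 over the settings). ilvG, a pseudogene of the same pathway, fell by 0.77 ± 0.08 in that fit (SE, adjusted p = 0.000873, 0.479 with all 9 libraries).

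Gene lists moved with AGGAA mainly where replicate 2 moved. The median log2 change was 1.38 for the 20 genes of the TCA cycle, which oxidises acetyl groups, and of the glyoxylate shunt (camera, adjusted p = 4.74e-06, 0.669 with an estimated correlation). It was 0.83 for 31 genes of aerobic respiration and ATP synthase (adjusted p = 1.61e-05, 0.669 with an estimated correlation). The median difference from the control mean in AGGAA replicates 1, 2 and 3 was 0.27, 2.47 and 0.18 for the TCA list, and 0.10, 1.63 and 0.12 for the aerobic list. By edgeR 0 members of these lists were called, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 15 TCA genes were higher, and 8 genes of the aerobic list were higher and 1 lower. DESeq2 called 0 members of either. The TCA list had a median of 0.26 without AGGAA replicate 2 (adjusted p = 4.02e-07, 0.688 with an estimated correlation), with 3 genes called higher, aceA, aceK and acnB, and 7 adjusted over the list alone. The aerobic list then had a median of 0.12 with 0 members called (adjusted p = 0.00216, 0.745 with an estimated correlation).

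Heat shock genes, for chaperones and proteases under sigma 32, had a median of 0.60 over 19 genes (camera, adjusted p = 3.95e-05, 0.669 with an estimated correlation), and 0.03, 1.22 and 0.19 in AGGAA replicates 1, 2 and 3. By edgeR 0 were called, 5 were higher at an unadjusted p under 0.05, and DESeq2 called 0. The 14 genes of branched-chain amino acid synthesis had a median of 0.50 (adjusted p = 0.00123, 0.669 with an estimated correlation), and 0.21, 0.94 and 0.08 in the replicates. Of these, 0 were called over all genes by edgeR, 2 adjusted over the list alone, 7 at an unadjusted p under 0.05 and 2 by DESeq2, all higher. The 28 genes of cysteine and sulfate assimilation had a median of 0.39 (adjusted p = 0.00123, 0.669 with an estimated correlation, 0.158 without replicate 2), and 0.12, 0.99 and 0.07 in the replicates. Again 0 were called by edgeR and by DESeq2, and 11 were higher at an unadjusted p under 0.05. Histidine synthesis, methionine synthesis and type 1 fimbriae had medians of 0.48, 0.51 and 0.85 (adjusted p = 0.00129, 0.00422 and 0.0112, 0.669 each with an estimated correlation). In replicate 2 their medians were 0.96, 1.13 and 1.61, and without it their adjusted p was 0.1, 0.258 and 0.271. edgeR and DESeq2 called 0 of their genes, and 1, 6 and 3 were higher at an unadjusted p under 0.05.

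Among the lists past the camera threshold, 3 had medians below 0. The 24 genes of toxin-antitoxin systems had a median of -0.27 (camera, adjusted p = 1.02e-06, 0.669 with an estimated correlation), and -0.05, -0.77 and -0.17 in AGGAA replicates 1, 2 and 3. Of these, 0 were called over all genes by edgeR, 3 were lower adjusted over the list alone, 4 at an unadjusted p under 0.05 and 3 by DESeq2. The acid resistance genes, which keep the cytoplasm from acidifying, had a median of -0.56 over 14 genes (adjusted p = 0.041, 0.72 with an estimated correlation), and 0.05, -2.60 and -0.07 in the replicates. Their adjusted p was 0.171 without control replicate 1, 0.061 without control replicate 3 and 0.965 without AGGAA replicate 2, where the median shrank to -0.06 and only camera's direction turned. The 52 genes of anaerobic respiration had a median of -0.39 and a mean of -0.01 (adjusted p = 0.0417, 0.712 with an estimated correlation), and 0.00, -2.03 and 0.02 in the replicates. Their adjusted p was 0.0563 without control replicate 2 and 0.748 without AGGAA replicate 2. By edgeR 0 genes of either list were called. At an unadjusted p under 0.05, 0 of the acid resistance genes differed, and 3 anaerobic respiration genes were lower and 7 higher, of which DESeq2 called 1 higher.

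The remaining 4 lists past the threshold had medians of 0.09 to 0.14. These were cell division (adjusted p = 0.0112, 0.693 with an estimated correlation), essential genes (0.0114, 0.72), lipopolysaccharide synthesis (0.0233, 0.712) and glycolysis (0.048, 0.669). Without AGGAA replicate 2 the adjusted p was 0.646 for cell division, 0.965 for lipopolysaccharide synthesis and 0.965 for essential genes, whose median shrank to 0.01 while camera's direction turned. Glycolysis lost its call without control replicate 2 or 3 or AGGAA replicate 1 or 3 (adjusted p = 0.113, 0.0723, 0.0677 and 0.183). Of 228 essential genes, 2 were called, glyQ and glyS, both lower, and trmD, lnt and ribA were lower as well without AGGAA replicate 2, 5 in all. glyQ and glyS were also the 2 called of the 23 aminoacyl-tRNA synthetase genes, a list with a median of 0.14, a mean of -0.09 and a camera adjusted p of 0.53. The other lists had adjusted p from 0.0543 (curli) to 0.861 (general stress).

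The comparison of ACCCA with control asks the same of the other guide. Among genes called with all 9 libraries, the 4 largest decreases were in yidD, rnpA, rpmH and ftsB. They lay in the runs of lowered neighbours rpmH-rnpA-yidD-yidC and truD-ispF-ispD-ftsB. rpmH (b3703), for ribosomal protein L34, fell from 175 ± 13.1 to 49.9 ± 3.69 CPM (SD, n = 3), a log2 change of -1.81 ± 0.16 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00197). rnpA (b3704), for the protein part of RNase P, which trims tRNA precursors, had a log2 change of -1.82 ± 0.17. yidD (b4557), for a protein of membrane protein insertion, had one of -1.93 ± 0.16 (SE, adjusted p = 0.00197 for both). ftsB (b2748), for an essential cell division protein, fell from 40.7 ± 2.57 to 12.1 ± 2.08 CPM (SD, n = 3), a log2 change of -1.75 ± 0.15 (SE, adjusted p = 0.00197). ispD (b2747) and ispF (b2746), for enzymes of isoprenoid precursor synthesis, fell by 1.53 ± 0.14 and 1.44 ± 0.10 (SE, adjusted p = 0.00197 and 0.00157). rsuA (b2183), for a 16S rRNA pseudouridine synthase, fell by 1.34 ± 0.12 (SE, adjusted p = 0.00197). yagB (b0266), a gene of a cryptic prophage, fell by 1.57 ± 0.18 (SE, adjusted p = 0.0055). zipA and ligA, neighbouring genes for a cell division protein and the DNA ligase and chosen after their values were seen, fell by 0.89 ± 0.08 and 0.61 ± 0.09 (SE, adjusted p = 0.00197 and 0.0271).

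Among genes called with all 9 libraries, the largest increase with ACCCA was in recN (b2616), for a protein of DNA break repair, which rose from 48.3 ± 3.36 to 161 ± 32.7 CPM (SD, n = 3), a log2 change of 1.74 ± 0.16 (SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00197). fes (b0585), for the enterobactin esterase, and fhuF (b4367), for a ferric siderophore reductase, rose by 1.55 ± 0.25 and 1.32 ± 0.22 (SE, adjusted p = 0.0303 and 0.0344). The level of fes was low, from 0.725 ± 0.181 to 2.1 ± 0.299 CPM, and fhuF rose from 12.1 ± 4.04 to 30.2 ± 2.24 CPM (SD, n = 3). In the fit without AGGAA replicate 2, cadB, for a lysine and cadaverine antiporter and chosen after its values were seen, rose further, by 1.84 ± 0.39 (SE, adjusted p = 0.00981, 0.108 with all 9 libraries, and 0.000368 to 0.427 over the settings). With all 9 libraries fdrA, uidC, ydjM, yjgL and ydeT rose by 1.06 to 1.24 (adjusted p = 0.0055 to 0.00967). Of these, fdrA had a low level, from 1.42 ± 0.215 to 3.36 ± 0.297 CPM (SD, n = 3). The calls of the 8 lower genes named by the rule and of recN and fdrA held with each library left out. That of fes ended without any 1 of the control or ACCCA libraries, and that of fhuF without any of these but control replicate 2. That of uidC ended without any of them but ACCCA replicate 2, and that of ydjM without replicate 1 or 3 of either group. That of yjgL ended without control replicate 1 or 3, and that of ydeT without control replicate 3. These adjusted p lay between 0.0509 (ydeT) and 0.204 (fhuF), the highest value of each of these genes over the settings being 0.153 for fes, 0.204 for fhuF, 0.0713 for uidC, 0.0781 for ydjM, 0.0614 for yjgL and 0.0509 for ydeT. All of these calls held without AGGAA replicate 2.

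**Figure D3:**
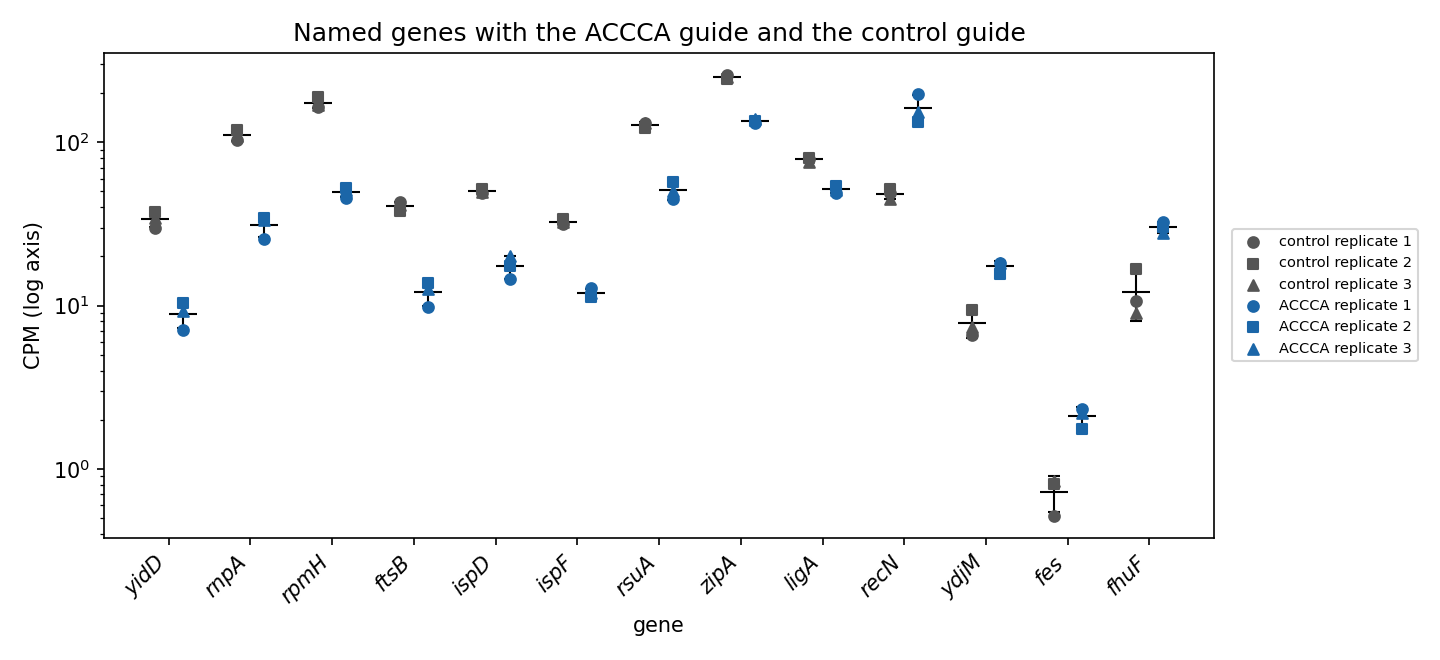
Points are CPM on a log axis in each library with the control guide (grey) and ACCCA (blue), with the mean and SD of 3 libraries as black bars. rpmH lies near 175 CPM with the control guide and near 49.9 CPM with ACCCA, and recN near 48.3 and 161 CPM.

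Many genes of the SOS response, which the LexA repressor holds down until DNA is damaged, rose with ACCCA. Of 27 genes, 12 were called higher, and 20 higher and 1 lower adjusted over the list alone (camera, adjusted p = 1.23e-21, 0.0417 with an estimated correlation). The median log2 change was 0.69, and the median differences from control in the ACCCA libraries were 0.76, 0.51 and 0.56, against -0.02, -0.15 and 0.00 in the AGGAA libraries. Besides recN, the called members included ydjM at 1.16 ± 0.15, tisB, for a membrane toxin, at 1.05 ± 0.17, and dinD at 0.90 ± 0.14 (SE, n = 3, edgeR adjusted p = 0.00878, 0.0336 and 0.0271). Chosen after their values were seen, recA, for the recombinase that triggers the response, rose by 0.83 ± 0.14, and dinB, for DNA polymerase IV, by 0.88 ± 0.17 (SE, adjusted p = 0.0336 and 0.0467). In the fit without AGGAA replicate 2, 22 were higher and 2 lower, lexA and dinF, and camera's adjusted p was 5.09e-15 (0.456 with an estimated correlation). The calls of tisB, dinD, recA and dinB ended without any 1 of the control or ACCCA libraries, with adjusted p from 0.0518 to 0.227. Those fits kept AGGAA replicate 2, which takes part in the shared spread. Without that library these calls held, with an edgeR adjusted p of 1.37e-05 for recA and 9.56e-05 for dinB.

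Some genes of iron uptake, which the Fur repressor holds down when iron is plentiful, also rose. Of 37 genes, 4 were called higher, and 12 adjusted over the list alone, while 14 were higher and 1 lower at an unadjusted p under 0.05, with a median log2 change of 0.34 (camera, adjusted p = 1.8e-06, 0.134 with an estimated correlation). The members were fes, fhuF, and tonB and exbB, for proteins that energise uptake across the outer membrane. tonB and exbB rose by 0.63 ± 0.11 and 0.60 ± 0.11 (SE, n = 3, edgeR adjusted p = 0.0355 and 0.0458). Leaving out AGGAA replicate 2, 12 were called higher (adjusted p = 0.000118, 0.488 with an estimated correlation). The calls of tonB and exbB ended without control replicate 1 or 3 or any 1 of the ACCCA libraries (adjusted p = 0.103 to 0.252), and held without AGGAA replicate 2.

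The medians of the ribosomal protein and glycolysis lists lay below 0 with ACCCA, and edgeR called few of their genes with all 9 libraries. Of 54 ribosomal protein genes, 4 were called lower, 20 adjusted over the list alone, 32 at an unadjusted p under 0.05 and 26 by DESeq2, with a median log2 change of -0.29 (camera, adjusted p = 4.32e-20, 0.134 with an estimated correlation). Besides rpmH these were rpmC at -0.70 ± 0.13, rplC at -0.63 ± 0.11 and rpsJ at -0.58 ± 0.10 (SE, n = 3, edgeR adjusted p = 0.0451, 0.0458 and 0.0355), which lay within 1 run of 11 lowered neighbours, rpsQ to rpsJ, in the fit without AGGAA replicate 2. In that fit 38 were lower and 1 higher. Of 13 glycolysis genes, 0 were called over all genes by edgeR, 9 were lower adjusted over the list alone and at an unadjusted p under 0.05, and 8 were lower by DESeq2. Their median was -0.28 (adjusted p = 1.76e-07, 0.134 with an estimated correlation). With AGGAA replicate 2 left out, 9 were lower, among them eno, for enolase, at -0.47 ± 0.07 and tpiA, for triosephosphate isomerase, at -0.39 ± 0.05 (SE, adjusted p = 0.00202 and 0.00105, 0.11 and 0.126 with all 9 libraries, at most 0.424 and 0.475 over the settings). The calls of rpmC, rplC and rpsJ ended without any 1 of the control or ACCCA libraries, with adjusted p from 0.0758 to 0.218, and held without AGGAA replicate 2.

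The acid resistance genes had the lowest median of the 8 lists past the threshold with ACCCA, -1.96 over 14 genes (camera, adjusted p = 3.66e-09, 0.555 with an estimated correlation). The median differences were -2.10, -1.70 and -2.09 in the ACCCA libraries, 0.32, -0.48 and 0.17 in the control libraries and -2.60 in AGGAA replicate 2. By edgeR 0 genes were called over all genes, 12 were lower adjusted over the list alone and at an unadjusted p under 0.05, and 11 were lower by DESeq2. When AGGAA replicate 2 was left out, 12 were called lower (adjusted p = 1.03e-11, 0.639 with an estimated correlation). gadB, for a glutamate decarboxylase, and hdeA, for a periplasmic acid chaperone, then lay at -2.72 ± 0.27 and -2.34 ± 0.27 (SE, n = 3, adjusted p = 0.000148 and 3e-04, 0.218 and 0.147 with all 9 libraries, at most 0.589 and 0.467 over the settings). Of 38 genes of the RpoS general stress response, 1 was called lower, aidB at -1.25 ± 0.23 (SE, adjusted p = 0.0458), and 13 adjusted over the list alone, with a median of -0.41 (adjusted p = 6.08e-10, 0.254 with an estimated correlation). The call of aidB ended without control replicate 1 or 3 or any 1 of the ACCCA libraries (adjusted p = 0.0989 to 0.218). Without AGGAA replicate 2 the call of aidB held, and 21 of the RpoS genes were lower.

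Heat shock genes and type 1 fimbriae genes had medians of -0.30 and -0.66 with ACCCA (camera, adjusted p = 0.0139 and 0.0161, 0.905 with an estimated correlation for both). In AGGAA replicate 2 their medians were 1.22 and 1.61. By edgeR 0 genes of either list were called, over all genes or adjusted over the list alone, 1 heat shock gene and 2 fimbriae genes were lower at an unadjusted p under 0.05, and DESeq2 called 1 and 0. Heat shock lost its call without ACCCA replicate 3 (adjusted p = 0.111) and fimbriae without control replicate 2 (adjusted p = 0.0828), and their adjusted p ran from 0.000801 and 0.000297 to 0.905 over the settings. A total of 6 of 19 heat shock genes and 7 of 9 fimbriae genes were called lower without AGGAA replicate 2. Of 228 essential genes, 6 were called lower, rnpA, ftsB, ispD, ispF, zipA and ligA, with a camera adjusted p of 0.21 for the list, and 30 were lower and 6 higher without AGGAA replicate 2 (adjusted p = 0.141). The other lists had adjusted p from 0.0622 (iron-sulfur cluster assembly) to 0.998 (methionine synthesis), and the 8 called lists kept their sign under every scaling. Of these others, 4 passed without AGGAA replicate 2, each at 0.639 with an estimated correlation. They were the TCA cycle (11 genes higher and 1 lower, adjusted p = 7.05e-05), aerobic respiration (5 and 1, 0.00161, with a median of 0.11 that turned to -0.03 with library totals as the scaling), iron-sulfur cluster assembly (7 lower, 0.0184) and branched-chain amino acid synthesis (1 lower, 0.0303).

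**Figure D4:**
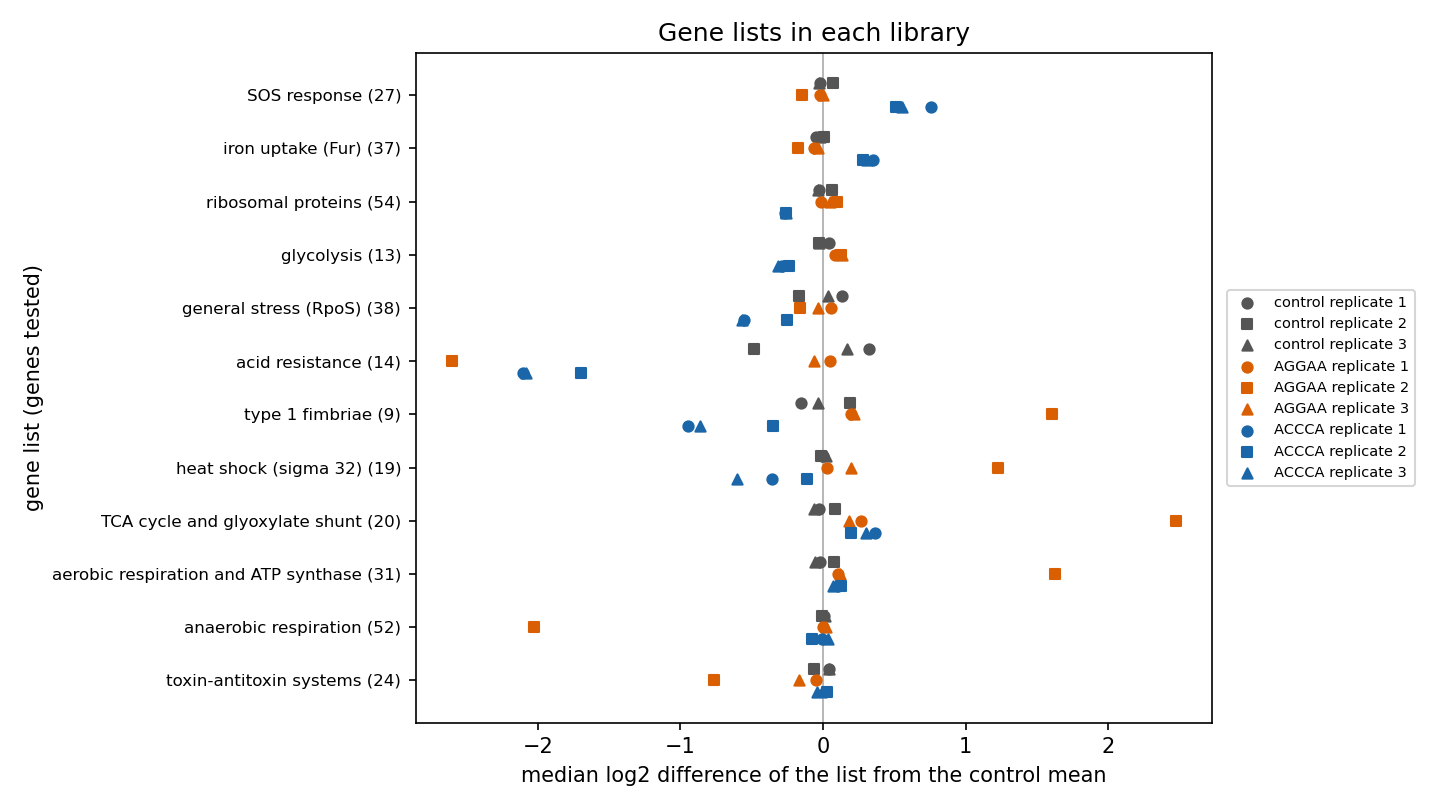
Each point is 1 library, placed by the median log2 difference of a gene list from the control mean, with colour for the guide, shape for the replicate number and the number of genes tested in brackets. The ACCCA libraries lie at 0.51 to 0.76 for the SOS response, and AGGAA replicate 2 (orange square) lies at 2.47 for the TCA cycle and at -2.60 for acid resistance.

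Among 4369 genes, 32 were lower and 30 higher with ACCCA than with the control guide (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 11 and 10 of them by at least 2-fold, and 523 had an unadjusted p under 0.05. DESeq2 called 180 lower and 123 higher. Without AGGAA replicate 2, which takes no part in the comparison but in the shared spread, 419 were lower and 330 higher, 61 and 22 by at least 2-fold, with 1295 at an unadjusted p under 0.05, and these held all 32 and all 30. Leaving out control replicate 1, 2 or 3 gave 13, 17 and 13 lower and 3, 10 and 3 higher. Leaving out ACCCA replicate 1, 2 or 3 gave 13, 15 and 15 lower and 7, 10 and 6 higher. With library totals as the scaling, the median of all genes moved to -0.133, and 33 were lower and 12 higher. At an adjusted p below 0.05, the authors' deposited DESeq2 table gives a lower level for 497 genes and a higher level for 417. A DESeq2 refit of 6 libraries, control and ACCCA, differed from its log2 changes by at most 1.93e-08. The 32 lowered genes formed 11 neighbouring pairs, against a mean of 0.21 and a maximum of 4 in 10000 random sets (permutation p = 0.0001, the smallest these draws can give). Of the raised genes, 29 formed 2 pairs, against a mean of 0.18 and a maximum of 3 (permutation p = 0.0139), and without AGGAA replicate 2 the raised genes formed 106 pairs, against a maximum of 43. Further lowered runs were bcr-rsuA-yejH at -1.34 to -0.81, ligA-zipA, insX-yagB and rplC-rpsJ.

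The comparison of AGGAA with ACCCA asks where the guides differ from each other. glyQ and glyS were lower with AGGAA, at -2.83 ± 0.14 and -2.47 ± 0.13 (SE, n = 3, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000104 for both), as was fdhD at -1.73 ± 0.13 (SE, adjusted p = 0.000457). yidD, rpmH and rnpA were higher with AGGAA, at 1.90 ± 0.16, 1.76 ± 0.16 and 1.72 ± 0.17 (SE, adjusted p = 0.000912, 0.00141 and 0.00174), as was ybaL at 1.77 ± 0.19 (SE, adjusted p = 0.00243). These 7 calls held under every setting tried. fimA, for the main subunit of type 1 fimbriae, was higher by 2.10 ± 0.42 (SE, adjusted p = 0.0343), with 1290 ± 756 against 302 ± 114 CPM (SD, n = 3). Over the settings its log2 change ran from 1.51 to 2.46. yqfG and yhaM were lower, at -2.50 ± 0.49 and -1.78 ± 0.34 (SE, adjusted p = 0.0318 and 0.0288). The call of fimA ended without any 1 of the ACCCA libraries (adjusted p = 0.0552 to 0.143) and that of yhaM without ACCCA replicate 1 or 3 (0.123 and 0.119). That of yqfG ended without AGGAA replicate 3 or any 1 of the ACCCA libraries (0.0588 to 0.123), and over all settings the adjusted p reached 0.163, 0.153 and 0.181.

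The lists that differed between the guides included those that moved with ACCCA. Of 27 SOS genes, 16 were lower with AGGAA, and 20 lower and 1 higher adjusted over the list alone (camera, adjusted p = 5.95e-13, 0.132 with an estimated correlation). Of 54 ribosomal protein genes, 14 were higher and 1 lower, and 29 and 1 adjusted over the list alone (adjusted p = 4.43e-12, 0.368 with an estimated correlation). Of 37 iron uptake genes, 5 were lower, and 13 lower and 1 higher adjusted over the list alone (adjusted p = 4.6e-07, 0.132 with an estimated correlation). Of 13 glycolysis genes, 3 were higher, and 11 adjusted over the list alone (adjusted p = 1.94e-07, 0.147 with an estimated correlation). Of 14 acid resistance genes, 1 was higher, and 9 adjusted over the list alone, with a median of 1.36 (adjusted p = 0.0026, 0.765 with an estimated correlation) and -2.60 in AGGAA replicate 2. Without that library their median was 1.84. In that fit gadB, gadC, hdeB and gadA, chosen after their values were seen, were called higher, at 2.23 to 2.68. Their edgeR adjusted p was 0.000206 to 0.000942, against 0.156 to 0.178 with all 9 libraries. In all, 84 genes were lower and 84 higher with AGGAA (edgeR), 30 and 23 by at least 2-fold, and 996 had an unadjusted p under 0.05. Leaving out AGGAA replicate 2, 329 were lower and 475 higher, 42 and 67 by at least 2-fold, with 1379 at an unadjusted p under 0.05, which held all 84 and all 84. Leaving out ACCCA replicate 1, 2 or 3 gave 20, 32 and 17 lower and 21, 35 and 22 higher, and leaving out AGGAA replicate 3 gave 50 and 69. DESeq2 called 303 and 392, and library totals as the scaling gave 43 lower and 68 higher.

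No gene was called with both guides when all 9 libraries were used: by edgeR 0 genes moved the same way and 0 opposite ways. At an unadjusted p under 0.05 with both guides, 39 genes moved the same way and 15 opposite ways, and DESeq2 called 6 and 5. Independent lists of the sizes of the edgeR calls would share 0.103 lower and 0.0206 higher genes, with 0.118 opposite. These values are no reference for the unadjusted lists, which hold 450 and 523 genes, or for the DESeq2 calls. The sharing expected of those longer lists was not computed, so their overlap does not show a shared response. Without AGGAA replicate 2, 5 genes were lower with both guides (4.5 for independent lists), 14 were higher with both (2.79) and 9 moved opposite ways (7.09). The shared higher genes, chosen after their values were seen, included aceA, for isocitrate lyase, at 0.51 ± 0.09 with AGGAA and 0.85 ± 0.08 with ACCCA (SE), and the neighbours mocA, ygfK, ssnA, ygfM, xdhD and xanQ, a region of purine breakdown and transport genes. The opposite genes included fdoG, at -1.20 ± 0.08 with AGGAA and 0.38 ± 0.07 with ACCCA (SE). Both comparisons share the control libraries. Simulated unchanged groups set against a shared set of simulated controls shared 0.06 genes on average and at most 1 without AGGAA replicate 2. Unchanged groups give few calls, so this count is no reference for the number of shared calls. Across genes, the log2 changes of both guides correlated at 0.132 with all 9 libraries and at 0.166 without AGGAA replicate 2. The simulated unchanged groups gave means of 0.489 and 0.407. Those groups hold no changes of a single guide, which lower a correlation, and their controls were drawn with the spread shared by all libraries. The simulated values therefore cannot decide whether the guides share changes. The covariance was 0.0202 against a simulated 0.0429 with all 9 libraries, and 0.014 against 0.0106 without AGGAA replicate 2. The control libraries are too few to split, so a part of the shared calls that comes from them was not measured.

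The vector features show the level of the dCas9 system itself. dCas9 RNA was at 51800 ± 4150 CPM in control, 68200 ± 19000 with AGGAA and 62000 ± 10200 with ACCCA (SD, n = 3, edgeR adjusted p = 0.486 and 0.822), and at 90000 in AGGAA replicate 2. The guide RNA feature was at 108000 ± 8330, 85100 ± 26300 and 111000 ± 8710 CPM (SD, n = 3, adjusted p = 0.522 and 0.989). GFPmut2, a gene for green fluorescent protein and chosen after its values were seen, was higher with ACCCA, at 259 ± 29.8 against 130 ± 6.95 CPM (SD, n = 3), a log2 change of 1.00 ± 0.11 (SE, adjusted p = 0.0055). The kanamycin resistance gene was at 113000 ± 1610 CPM with ACCCA and 64700 ± 10900 in control (SD, n = 3, adjusted p = 0.198, and 0.00256 without AGGAA replicate 2).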

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

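The fits without AGGAA replicate 2 for ACCCA, those joining that omission with DESeq2 or the replicate block, and the fits without vector features were chosen only after the data were seen. For named genes, 1607 values kept their side of the threshold, 283 newly passed it and 149 no longer passed it. No value past the threshold changed sign, but values short of it did for bssS (-0.23 to 0.75 over the settings) and lacZ (-0.15 to 0.39) with AGGAA. For the called lists 170 values held, 66 no longer passed and for 2 the direction camera gives turned while the median kept its sign: essential genes and acid resistance with AGGAA, without AGGAA replicate 2 (adjusted p = 0.965 for each), against 4.43e-05 and 0.0036 without AGGAA replicate 1. RLE size factors, no count filter, a mean of at least 50 counts, no rRNA and tRNA features and no vector features kept every gene count within 1.5 times its value with all 9 libraries. DESeq2 called 62 lower and 39 higher for AGGAA, 180 and 123 for ACCCA, 303 and 392 for AGGAA against ACCCA, and an overlap of 6 genes in the same and 5 in opposite directions. With only the 6 libraries compared the counts were 5 and 0, 431 and 372, and 12 and 14. Of these only the ACCCA counts rose, and that fit leaves out AGGAA replicate 2. Library totals gave 12 higher for ACCCA and 43 lower for AGGAA against ACCCA. The replicate number as a block gave 9 lower for AGGAA, 15 and 6 for ACCCA, and 38 and 38 between the guides. Libraries of the same number correlated at -0.117 to 0.174 in their deviations from the group mean, and those of different numbers at -0.173 to 0.11. Same-number values were 0.17, 0.174 and 0.098 between control and AGGAA, and -0.117, -0.028 and 0.03 between control and ACCCA. Deviations from means of 3 libraries are a weak check, so pairing is neither shown nor excluded. Without AGGAA replicate 2, DESeq2 gave 74 and 78, 484 and 378, and 387 and 525, and the block 48 and 48, 438 and 352, and 332 and 466. Leaving out 1 library at a time gave 6 to 47 lower and 0 to 37 higher for AGGAA, 13 to 419 and 3 to 330 for ACCCA, and 17 to 329 and 21 to 475 between the guides. The highest of each was without AGGAA replicate 2. The lowest were without a control library for AGGAA, without control replicate 1 or 3 or, for lower genes, ACCCA replicate 1 for ACCCA, and without ACCCA replicate 3 (lower) or 1 (higher) between the guides. The called lists numbered 8 to 19 for AGGAA and 8 to 12 for ACCCA with 1 library left out, 0 and 1 with an estimated correlation, and 0 and 4 by fry. The overlap ran from 0 to 19 genes in the same and 0 to 9 in opposite directions, the highest without AGGAA replicate 2. In the ACCCA comparison AGGAA replicate 2 takes part only in the shared spread, and without it the counts rose to 419 and 330. The medians barely moved, at -1.96 in both fits for acid resistance and 0.69 and 0.70 for SOS. Leaving out any 1 control or ACCCA library lowered the counts. These values argue against a smaller number of libraries as the cause of that rise. For the other shifts, apart from the smaller number of libraries in some fits, the cause was not tested. The planned test of guide seed sites upstream of lowered genes, with its alternatives, was not run, because no genome sequence was used here. In simulated counts with all 9 libraries, 45% of ACCCA genes and 60% of AGGAA genes changed by -1 on the log2 scale were called, so smaller changes were mostly not detectable.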

Other observations

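The tests of a wrong label, of growth state and of a faster-growing culture, that of lexA and that of neighbouring genes were chosen only after the results were seen. The fit without AGGAA replicate 2 for ACCCA was too, and the runs and the fuc, yde and ace genes named here were chosen after their values were seen. In that fit, several runs of neighbouring genes were lower with ACCCA than with the control guide. The 7 genes citT to citC, for citrate uptake and fermentation, lay at -2.21 to -1.03, with citX at -2.21 ± 0.18 (SE, n = 3, edgeR adjusted p = 5.15e-05, 0.273 with all 9 libraries, and 2.68e-33 to 0.631 over the settings). None of these 7 was called with all 9 libraries (adjusted p from 0.182 for citG to 0.377 for citF). The 10 genes hyaA to appA, among them those for hydrogenase 1 and a cytochrome oxidase, lay at -2.01 to -1.43 (with all 9 libraries not called, adjusted p from 0.207 for appA to 0.556 for hyaE). The genes narG, narH, narJ and narI, for nitrate reductase, lay at -1.13 to -0.97 (not called with all 9 libraries, adjusted p from 0.772 for narI to 0.827 for narJ). The 8 genes slp to gadE, of the acid fitness region, lay at -2.44 to -1.63 (not called with all 9 libraries, adjusted p from 0.147 for hdeA to 0.293 for gadE).

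The hya and nar genes do not stand for anaerobic respiration as a whole. Of the 52 genes of that list, 14 were lower and 6 higher with ACCCA in the fit without AGGAA replicate 2, with a median of -0.01 (camera, adjusted p = 0.266). With all 9 libraries edgeR called 0, 0 were lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called 1 higher (camera, adjusted p = 0.608). In the fit without AGGAA replicate 2 the runs fdoI-fdoH-fdoG and fumB-dcuB were higher, at 0.23 to 0.38 and 0.21 to 0.37. The 6 genes fucO to fucU, for fucose use, lay at 0.35 to 1.05 (not called with all 9 libraries, adjusted p from 0.127 for fucK to 0.948 for fucO). Those from ydeP to ydeT lay at 0.68 to 1.07, of which only ydeT was called with all 9 libraries (adjusted p = 0.0055). In that same fit the glyoxylate shunt genes aceB, aceA and aceK rose by 0.80 ± 0.07, 0.85 ± 0.08 and 0.81 ± 0.07 (SE, n = 3, adjusted p = 5.99e-05, 9.8e-05 and 5.87e-05, 0.766, 0.817 and 0.763 with all 9 libraries, at most 1 over the settings).

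Of the genes counted, 86 had 0 counts in all 9 libraries. A total of 38 of them lie next to each other, from ydfK to intQ, the region of the Qin prophage, between ydfI with 4376 counts and rspB with 2060. All 23 genes of the Qin list had 0 counts, which allows a level of up to 0.0123 CPM over all libraries and 0.159 CPM in the smallest one. The next longest run was 3 genes, insertion-sequence genes among them. Of 22 Rac prophage genes 1 had no count, and of 23 e14 prophage genes 0 had none.

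AGGAA replicate 2 stood apart from the other 8 libraries. A library of another guide under this label is argued against, since the 13 genes lowered at least 2-fold without it had a median of -2.04 in it, below every control library in all 13. Depth is argued against, since thinning to its total left AGGAA replicates 1 and 3 at a distance of 0.305, against 1.04 for replicate 2. A few abundant transcripts are argued against, since its distance over protein-coding genes and pseudogenes was 1.04, against 1.05 over all genes. A candidate explanation is another growth state at harvest. The 3 lists named for it lay in the direction named, against 10000 random lists. Their differences were 1.44 for aerobic respiration, 2.29 for the TCA cycle and -2.52 for acid resistance. Other lists also lay at an end of the random lists: anaerobic respiration at -1.74, heat shock at 1.17 and cysteine and sulfate assimilation at 1.14. Ribosomal proteins at 0.10 and SOS at -0.14 did not (percentiles 91.48 and 20.92). The 3 lists were chosen after they were seen, and no record of the cultures was used here.

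The median of the acid resistance list was lower in each ACCCA library than in the control libraries, though camera's adjusted p was 0.555 with an estimated correlation. The lower depth of the ACCCA libraries is argued against, since with all libraries thinned to the smallest total the median was -1.96. A larger share of vector counts is argued against, since without vector features and with library totals as scaling it was -2.03. In an earlier, faster-growing culture ribosomal protein genes would be higher, and their highest median in an ACCCA library was -0.26, below the lowest control library at -0.04. Their list holds runs of lowered neighbours, such as rpsQ to rpsJ at -0.73 to -0.56 without AGGAA replicate 2. The medians argue against such a culture as the whole cause only if the guide does not itself lower these genes, which was not tested. An effect of the guide may remain as a hypothesis, and other differences between the cultures were not tested.

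The median of the SOS list was higher in each ACCCA library than in the control libraries, while lexA and dinF went the other way. Depth and vector counts are argued against, since the median was 0.67 after thinning and 0.63 without vector features. DNA damage alone, with lexA transcribed like its regulon, is argued against by lexA at -0.25 ± 0.07 (SE, n = 3, edgeR adjusted p = 0.0338 without AGGAA replicate 2, 0.337 with all 9 libraries), which rests on 1 gene. Lower levels of lexA may therefore be part of it, and lower ligA, at -0.61 ± 0.06 in the same fit, is another candidate explanation that was not tested.

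Genes lowered by ACCCA formed 11 neighbouring pairs, more than the 4 that 10000 random gene sets reached at most, and the raised genes formed 2, of at most 3 in random sets (permutation p = 0.0139). Because neighbouring genes can share a transcript and the random sets draw genes singly, the pairs do not show where the guide acts. Each comparison has 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. The real split gave 17 calls for AGGAA against control, 62 for ACCCA against control, 168 for AGGAA against ACCCA and 749 for ACCCA against control without AGGAA replicate 2, and the highest of the other splits gave 0 each time, so 1 of 10 was as large. Each other split mixes libraries of different guides within a group, which widens the spread, so its 0 calls say little about chance.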
